A study of Mus musculus with 8 samples.

How the data were processed

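Single-cell RNA sequencing measured gene expression in 8 libraries of dissociated mouse gliomas, 3 labelled PDGFB-WT overexpression, 2 labelled PDGFB-NLS overexpression and 3 labelled Control. The deposited values were raw UMI counts per gene and cell barcode, with no normalization, which the authors made with Cell Ranger 8 against mm10 per the labels. The deposited tables also listed cell barcodes, and gene identifiers with symbols, as text without a measurement. The feature table held 31055 features, among them the added sequences egfp and pdgfb_nls. The labels name the 3′ kit chemistry as v3 in 1 place and as v3 or v4 in another, without saying which library had which. How the barcodes of each library had been selected is not given in the sources used here.

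The files held 260517 barcodes. Total UMI counts were 89420504, 87401760 and 20428887 for PDGFB-WT replicates 1 to 3, 34911520 and 40843338 for PDGFB-NLS replicates 1 and 2, and 13433920, 26071040 and 16269842 for Control replicates 1 to 3. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 69238 cells. Scrublet as implemented in scanpy was run per library with an expected doublet rate of 0.06. It removed 0.016% and 0.005% of cells in PDGFB-WT replicates 1 and 2, shares at which the caller had not separated doublets, and 0.412% to 2.48% in the other libraries. The remaining 68837 cells were scaled to 10000 counts per cell, log-transformed and reduced to 30 principal components of 2000 variable genes, then clustered with the Leiden algorithm at resolution 1 on a graph of 15 neighbours. No integration of libraries was applied.

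Clusters were named from 17 marker lists. The score of a list was the mean log2 ratio of its markers between a cluster and all other cells, with a pseudocount of 10 CPM. A name needed a score of at least 1 and at least 3 markers at 2-fold. It was withheld where a second list scored above 0.75 of the best with as many raised markers, where the 10 leading genes held more markers of another list, or where depth was low and no marker was among those 10. Names carry the ending -like because they rest on markers alone. Of 27 clusters 22 were named, giving 13 classes with 39837 cells, and the 5 unnamed clusters were left out of the tests by class. The thresholds of the naming score were set after the data had been seen. Shares of cells use the named cells of a library as denominator.

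Counts were summed per library and class, and a class entered a test where at least 20 of its cells were present in at least 2 libraries of each group. edgeR 4.0.16 fitted quasi-likelihood models with TMM scaling, its default expression filter and all groups in 1 model. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 were called. PDGFB-WT had fewer than 20 astrocyte-like, microglia-like and endothelial-like cells in replicates 1 and 2, so PDGFB-WT was not compared in these classes. DESeq2 1.42.0 was run beside edgeR. Gene lists, 34 in all, were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, and each list's genes were also adjusted over the list alone. Shares of cells were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 libraries against 3, 0.2 for 3 against 2 and 0.0357 for 5 against 3. Adjusted values of these tests cover the 13 classes of a comparison.

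For cycling cells, the UMIs of each cell were thinned at random to 1000 before cells with a UMI of Mki67 or Top2a were counted. Intervals for shares in single libraries are exact Clopper-Pearson intervals at 95%. Intervals and floors cover counting error only. Where a group had 0 UMIs of a gene, the fold is a lower bound against a floor of 3 UMIs over the summed class counts of the group. Medians of lists with members at 0 to 3 UMIs in a group are also given with those members at that bound where this changed the median. Values beside genes are TMM-scaled CPM, mean ± SD over libraries. Transgene and Pdgfb values of single libraries, clusters and barcodes with few UMIs are CPM without TMM scaling, and log2 changes carry their standard error (SE). Free RNA was gauged in barcodes with at least 500 but under 1000 UMIs of the same library, as the ratio of the CPM of a gene in a class to its CPM in those barcodes.

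Named genes were chosen by a rule fixed before the data were examined, as were the groups, comparisons, marker lists, gene lists and most alternatives. It took Pdgfb, Pdgfa, Pdgfra, Pdgfrb and the added sequences where tested. It then took up to 12 genes on each side with the largest change among called genes with at least 20 CPM in a group and no overlap between groups, leaving out gene models without a common name and immunoglobulin, T cell receptor, haemoglobin and sex-linked genes. It also took the 4 genes with the smallest p of each list, and the 10 with the smallest p where fewer than 5 genes passed. The text names part of the genes the rule selected. Gene positions came from a GENCODE annotation of mm10.

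Alternatives were another scaling (RLE), no expression filter, DESeq2, models of only the groups compared, a replicate block, equal numbers of cells per library, thinning to equal depth, stricter and looser cell filters, doublets kept, Leiden resolution 2 and leaving out each library. Treating PDGFB-WT replicates 1 and 2 as 1 sample, using all kept cells as denominator, and models of only the 2 groups for endothelial-like cells under other filters and a finer clustering were added after the data had been seen. The models were tested on simulated data with known changes in 100 genes. At an 8-fold change they recovered 78% (PDGFB-WT with PDGFB-NLS), 82% (PDGFB-WT with Control) and 79% (PDGFB-NLS with Control) in OPC-like cells. At a 2-fold change they recovered 2%, 9% and 2%. In microglia-like and astrocyte-like cells they recovered 29% and 45% of 2-fold changes. Software was R 4.3.3, Python 3.11.15, scanpy 1.11.5, scipy 1.17.1 and matplotlib 3.10.9.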

Results

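The data were single-cell RNA profiles of dissociated mouse gliomas made by piggyBac in utero electroporation, in which a transposon carrying the transgene is delivered into embryonic brain cells. The labels give the 3 groups named above. PDGFB is a growth factor that activates PDGF receptors, which oligodendrocyte precursor cells (OPCs) carry. NLS is the usual short form of nuclear localisation signal, and how this construct was changed is not given in the sources used here. The tissue label of the Control libraries is also glioma. The series title concerns chromatin binding by PDGFB, mutant IDH and chromosome instability, and no library label names an IDH genotype. The labels do not state that replicates were separate animals, and they give no ages. Parts of the deposited names that may stand for ages differ between PDGFB-WT and PDGFB-NLS and are lacking for Control, so a difference in age stays open in every comparison of groups.

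Total UMI counts ranged from 13433920 to 89420504. The number of kept cells was 19289, 19262 and 6615 in PDGFB-WT replicates 1 to 3, 7592 and 7155 in PDGFB-NLS, and 2206, 4689 and 2430 in Control. Kept cells had a median of 1249, 1245.5 and 1782 UMIs in PDGFB-WT, 2280 and 3330 in PDGFB-NLS, and 4000, 2703 and 4390 in Control. PDGFB-WT replicates 1 and 2 differed from each other far less than from replicate 3. Over the sum of all cells, chi-squared per degree of freedom was 13.8 between replicates 1 and 2, and 533 and 530 between these and replicate 3. It was 187 between the PDGFB-NLS replicates. Clusters without a cell type name held 74.5% and 72.7% of cells in PDGFB-WT replicates 1 and 2 and 1.60% in replicate 3. Group means of this share were 49.6% ± 41.6 (SD, n = 3) in PDGFB-WT, 2.02% ± 0.220 (SD, n = 2) in PDGFB-NLS and 2.57% ± 0.659 (SD, n = 3) in Control. PDGFB-WT libraries shared 439 to 2263 cell barcodes with each other and at most 2 with any other library, while the other libraries shared 11 to 104 among themselves. Libraries that drew on the same set of barcodes would overlap across groups too, so PDGFB-WT drew on another set than PDGFB-NLS and Control. A difference between kit versions could give this, and the labels do not say which library had which. A technical difference thus coincided with the group. Its effect stays open in every comparison of PDGFB-WT with another group. A run difference between PDGFB-NLS and Control was not tested and stays open too.

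The transgene features were counted in OPC-like cells of both PDGFB groups and had no UMI in OPC-like cells of Control. By library and by cluster they are given as CPM of the summed cells without TMM scaling. In OPC-like cells, egfp reached 3110, 3259 and 516 CPM in PDGFB-WT replicates 1 to 3 and 17118 and 5266 CPM in PDGFB-NLS replicates 1 and 2. The pdgfb_nls feature was counted in both groups, at 5291, 6381 and 699 CPM in PDGFB-WT and 832 and 680 CPM in PDGFB-NLS. It was highest in PDGFB-WT replicates 1 and 2, against its name, so it did not separate the labelled constructs. The mouse Pdgfb gene (ENSMUSG00000000489, mm10 chromosome 15, 79995874 to 80014977, minus strand, protein coding) did separate them, with 713, 834 and 41.2 CPM in PDGFB-WT against 0 and 0.195 CPM in PDGFB-NLS. A UMI of egfp was seen in 86.3%, 87.8% and 16.2% of OPC-like cells in PDGFB-WT, and in 24.5% and 23.8% in PDGFB-NLS. Free RNA set the background of this share. In PDGFB-WT replicates 1 and 2 it was 62.9% and 65.1% in T/NK-like cells, which had a median of 1682.5 and 1711 UMIs against 2787 and 2619.5 in OPC-like cells. In PDGFB-NLS it was 3.66% and 4.23% in microglia-like cells, with medians of 2222 and 2667.5 UMIs against 4253 and 5817.5 in OPC-like cells. In PDGFB-WT replicate 3 it was 0.157% in microglia-like cells, with 1743 UMIs against 2503.5. The features did not mark the class as a whole or alone. Cluster 0, with 29.4% and 28.1% of the OPC-like cells of PDGFB-WT replicates 1 and 2, had egfp at 439 and 511 CPM, not above the 654 and 603 CPM of T/NK-like cells, while cluster 4 had 4093 and 4256 CPM. Neuroblast-like cells of PDGFB-NLS also had egfp, at 17140 and 3047 CPM.

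Shares of cell types were compared between groups. OPC-like cells, the lineage with Pdgfra and Olig genes as markers, were 45.9% ± 36.1 (SD, n = 3) of named cells in PDGFB-WT, 8.42% ± 4.03 (SD, n = 2) in PDGFB-NLS and 1.30% ± 0.742 (SD, n = 3) in Control. The libraries were at 67.0%, 66.5% and 4.28% in PDGFB-WT, 5.58% and 11.3% in PDGFB-NLS, and 2.08%, 0.599% and 1.23% in Control. Most cells of PDGFB-WT replicates 1 and 2 had no name. Of all kept cells the shares were, in the same order, 17.1%, 18.2% and 4.22%, 5.47% and 11%, and 2.01%, 0.586% and 1.2%, which brings the groups closer. All 5 PDGFB libraries together (30.9% ± 32.8) lay above all 3 Control libraries (exact permutation p = 0.0357, the smallest this design allows, adjusted p = 0.371). The difference was 44.6 percentage points for PDGFB-WT with Control (exact permutation p = 0.1, adjusted p = 0.26). It was 7.12 for PDGFB-NLS with Control (exact permutation p = 0.2, adjusted p = 0.65) and 37.5 for PDGFB-WT with PDGFB-NLS (exact permutation p = 0.6, adjusted p = 0.709). With 3 against 3 or 2 libraries p could not go below 0.1 or 0.2. The PDGFB-WT mean rested on replicates 1 and 2, and without replicate 1 or replicate 2 it was 35.4% or 35.7%. The difference between PDGFB-WT and PDGFB-NLS was then 27.0 or 27.2 percentage points, and without replicate 3 it was 58.3.

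Immune and glial classes also differed among libraries. T/NK-like cells were 14.2% of named cells in PDGFB-WT replicates 1 and 2 and 0.0158% in replicate 3, and their cluster held no cell of PDGFB-NLS or Control. This 0 follows from the clusters and sets no limit on T/NK cells, since at Leiden resolution 2 a neutrophil-like cluster with T/NK markers as its second list (score 3.73) held 13 to 21 cells of each of these 5 libraries. Macrophage-like cells were 11% and 11.7% in PDGFB-WT replicates 1 and 2 and 0.0158% in replicate 3. Their near absence outside replicates 1 and 2 came with a withheld name. Cluster 22, with markers of macrophages and neutrophils, had none and held 68 cells of PDGFB-WT replicate 3, 97 and 111 of PDGFB-NLS and 42, 82 and 39 of Control, and at resolution 2 a macrophage-like cluster held 50, 84, 94, 27, 61 and 26 cells of these libraries. Astrocyte-like cells were 16.2% in PDGFB-WT replicate 3, 32.3% ± 6.72 (SD, n = 2) in PDGFB-NLS and 35.2% ± 1.10 (SD, n = 3) in Control, and PDGFB-WT replicates 1 and 2 held 0 and 1 such cell, the first allowing up to 0.061%. Microglia-like cells were 30.1% in PDGFB-WT replicate 3, 35.1% and 20.1% in PDGFB-NLS, and 25.1%, 24.3% and 20.1% in Control, with none in PDGFB-WT replicates 1 and 2, which allows up to 0.061% and 0.0571%. These limits concern cells that cluster with these classes, while most cells of replicates 1 and 2 had no class name. Neuroblast-like cells were 5.01% ± 0.784 (SD, n = 2) in PDGFB-NLS and 0.992% ± 0.226 (SD, n = 3) in Control (exact permutation p = 0.2, adjusted p = 0.65). None of these shares passed its test after adjustment.

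**Figure D1:**
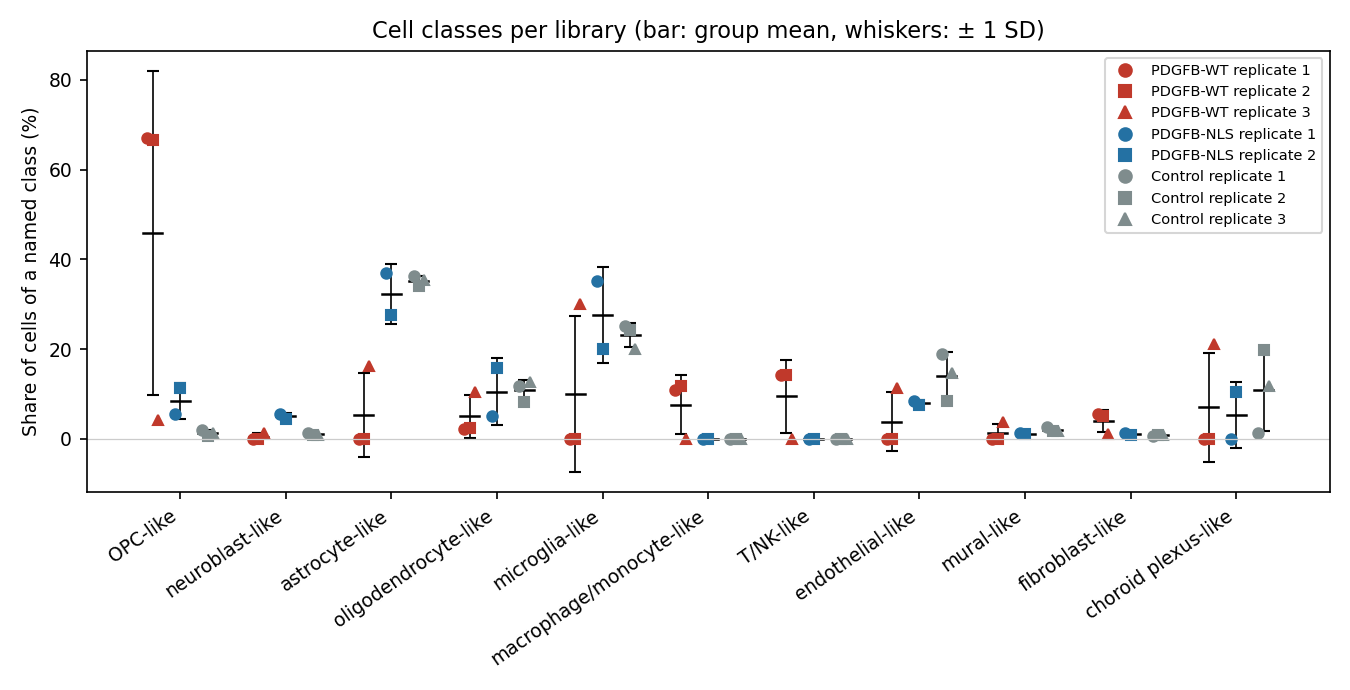
Each point is 1 library (PDGFB-WT, PDGFB-NLS or Control) and gives its share of cells of a named class in percent, for 11 cell classes on the horizontal axis, with a bar for the group mean and whiskers for 1 SD. OPC-like cells are at 67.0%, 66.5% and 4.28% of named cells in PDGFB-WT replicates 1 to 3.

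OPC-like cells with a UMI of Mki67 or Top2a, genes of dividing cells, were counted after thinning each cell to 1000 UMIs. They were 7.33% ± 0.962 (SD, n = 2) in PDGFB-NLS, 3.07% ± 0.751 (SD, n = 3) in PDGFB-WT and 2.38% ± 2.07 (SD, n = 3) in Control. The PDGFB-NLS libraries, at 8.01% (Clopper-Pearson 95% interval 5.58 to 11.1) and 6.65% (5.01 to 8.63), lay above the PDGFB-WT libraries at 3.46% (2.86 to 4.14), 3.55% (2.96 to 4.21) and 2.21% (0.814 to 4.74). The difference of PDGFB-WT minus PDGFB-NLS was -4.26 percentage points (exact permutation p = 0.2, the smallest possible). It was 4.95 for PDGFB-NLS minus Control (exact permutation p = 0.2) and 0.687 for PDGFB-WT minus Control (exact permutation p = 0.8). Control had 0 of 44, 1 of 27 and 1 of 29 such cells, so its shares were imprecise, with an upper Clopper-Pearson bound of 8.04% for the first. The difference between PDGFB-WT and Control was -0.50 to 1.35 when each library was left out in turn. As a background, the share was 0.462% and 1.00% in microglia-like cells of PDGFB-NLS, 0.575% in those of PDGFB-WT replicate 3 and 0.752% to 0.84% in those of Control. In PDGFB-WT replicates 1 and 2 it was 4.63% (1.52 to 10.5) and 3.25% (0.893 to 8.12) in oligodendrocyte-like cells, 4.81% and 4.72% in macrophage-like cells, which may divide, and 1.11% (0.23 to 3.21) and 3.31% (1.52 to 6.19) in fibroblast-like cells. The OPC-like shares there lay within or near these intervals and were not shown to exceed free RNA. All cells were compared at 1000 UMIs.

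PDGFB-WT was compared with PDGFB-NLS in OPC-like cells. Pdgfb was 582 ± 476 CPM in PDGFB-WT (SD, n = 3) and 0.106 ± 0.150 CPM in PDGFB-NLS (SD, n = 2), where its count was 1 UMI (adjusted p = 0.00848). Pdgfa, which encodes another ligand of PDGF receptors (ENSMUSG00000025856, mm10 chromosome 5, 138976014 to 138997370), fell by 2.98 on the log2 scale ± 0.79 (SE, adjusted p = 0.0192), from 201 ± 77.4 CPM in PDGFB-NLS to 27.0 ± 9.05 CPM in PDGFB-WT. It lost this call without PDGFB-WT replicate 1 or 2 or either PDGFB-NLS replicate, with PDGFB-WT replicates 1 and 2 as 1 sample, with equal cells per library (fell by 0.97) and when thinned to equal depth. At 5% mitochondrial UMIs, at 2000 UMIs and at Leiden resolution 2 it was not called either, and fell by 0.17, 0.30 and 0.21. Pdgfra, the receptor of OPCs (ENSMUSG00000029231, mm10 chromosome 5, 75152292 to 75198215), was 490 ± 125 and 291 ± 29.4 CPM (adjusted p = 0.201). Feedback regulators of receptor and MAP kinase signalling were higher in PDGFB-WT, among them Spry1 (88.3 ± 26.5 against 13.2 ± 4.49 CPM, adjusted p = 0.00614), Spred2 (log2 change 2.55 ± 0.43), Etv4 (1.78 ± 0.31) and Dusp6 (2.31 ± 0.50). Of 14 tested genes of this list 8 rose and none fell, 10 adjusted over the list alone (median 1.2, adjusted p = 0.00407, adjusted p = 0.502 with an estimated correlation).

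Genes of cell division were lower in PDGFB-WT than in PDGFB-NLS, while none of their 4 lists kept its call with an estimated correlation (adjusted p = 0.502 for each). Tpx2, a spindle assembly factor, was at 15.6 ± 1.36 against 89.5 ± 39.1 CPM (log2 change -2.53 ± 0.43, adjusted p = 0.00651), and the mitotic cyclin gene Ccnb1 at 5.24 ± 0.0760 against 33.6 ± 15.7 CPM (-2.63 ± 0.46, adjusted p = 0.00665). Kif20b, a mitotic kinesin gene, fell by 2.77, the kinetochore gene Nuf2 by 2.24, the spindle checkpoint kinase gene Bub1 by 3.33 and the replication clamp gene Pcna by 2.72. Of 20 G2/M genes 15 fell (20 adjusted over the list alone, median -2.34, adjusted p = 1.17e-05), and of 17 spindle checkpoint and kinetochore genes 15 fell (15 adjusted over the list alone, median -2.24, adjusted p = 1.17e-05). Of 18 S phase genes 9 fell (11 fell and 1 rose adjusted over the list alone, median -1.18, adjusted p = 0.0025). Of 21 cohesin and condensin genes 8 fell and 1 rose, and as many did adjusted over the list alone (median -0.50, adjusted p = 0.0221).

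Interferon response and antigen presentation genes were higher in PDGFB-WT, while none of their 3 lists kept its call with an estimated correlation (adjusted p = 0.502 for each). Bst2, an antiviral membrane protein gene, was at 266 ± 209 against 6.43 ± 0.0722 CPM (adjusted p = 0.00848), the proteasome subunit gene Psmb9 at 158 ± 130 against 2.96 ± 0.0218 CPM, and the peptide transporter gene Tap2 at 36.6 ± 16.0 against 5.36 ± 1.58 CPM. Nlrc5, a transactivator of MHC class I genes, had 0 UMIs in PDGFB-NLS and was at least 94.2-fold higher in PDGFB-WT. Ifit1 was at 44.0 CPM against 0.213 CPM (2 UMIs), Oasl2 at 67.3 against 0.106 CPM (1 UMI) and Usp18 at 30.2 against 0.106 CPM (1 UMI). All 18 interferon genes tested rose (median 5.67, or 5.57 with 9 members at their bound, adjusted p = 0.00049), as did all 10 MHC class I genes (median 4.82, adjusted p = 0.00381) and all 7 MHC class II genes (median 6.73, or 6.18 with 1 member at its bound, adjusted p = 0.0205), each also adjusted over its list alone. Over the 28 called interferon and MHC class I genes, the median ratio of OPC-like cells to barcodes with few UMIs was 1.03, 1.00 and 0.212 in PDGFB-WT replicates 1 to 3. Immune cell genes moved with this group. Cd74, the MHC class II invariant chain gene, was at 809 ± 693 against 0.826 ± 0.335 CPM, and its ratio to barcodes with few UMIs was 0.339, 0.375 and 0.103. The complement gene C4b rose by 7.87 ± 1.28. All 11 complement and phagocytosis genes rose (median 3.31, adjusted p = 0.000101), as did 9 of 11 homeostatic microglia genes (median 2.22, adjusted p = 3.41e-06), both with as many adjusted over the list alone and adjusted p = 0.502 with an estimated correlation.

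Part of the myelin and late oligodendrocyte genes were lower in PDGFB-WT. Mog, a myelin glycoprotein gene, was at 6.25 ± 8.02 against 126 ± 91.6 CPM (adjusted p = 0.0105), Ugt8a, an enzyme gene of myelin lipid synthesis, at 144 ± 64.4 against 837 ± 240 CPM, and Tmem125 at 3.17 ± 5.08 against 74.5 ± 32.0 CPM. The cholesterol enzyme gene Cyp51 fell by 2.97 and Il23a, a cytokine subunit gene, by 7.30 (0.193 against 49.1 CPM). Of 14 myelin genes 7 fell (7 adjusted over the list alone, median -2.45, adjusted p = 0.00722, adjusted p = 0.546 with an estimated correlation), and of 15 cholesterol synthesis genes 4 fell (3 adjusted over the list alone, median -1.50, adjusted p = 0.0149, adjusted p = 0.613 with an estimated correlation). The developmental transcription factor genes were higher, Sox11 at 303 ± 189 against 33.1 ± 3.19 CPM and Sox4 at 275 ± 37.4 against 87.4 ± 12.1 CPM. The matrix gene Tnc rose by 3.37 ± 0.64, the galectin gene Lgals3 was at 17.8 against 0.213 CPM (2 UMIs) and the heparan sulfate enzyme gene Ndst3 at 153 against 0.213 CPM (2 UMIs). Of 13 mesenchymal genes 12 rose (12 adjusted over the list alone, median 3.37, adjusted p = 0.00194, adjusted p = 0.502 with an estimated correlation). The immediate early genes Jun and Egr1 rose by 2.52 ± 0.36 and 2.49 ± 0.56, and 8 of 14 dissociation stress genes rose (8 adjusted over the list alone, median 1.32, adjusted p = 0.0177, adjusted p = 0.502 with an estimated correlation). Ribosomal protein genes Rpl10 (11.7 ± 6.69 against 1470 ± 39.4 CPM), Rps2 and Rpl21 (17.6 ± 7.33 against 1753 ± 220 CPM) were counted far less in PDGFB-WT. Of their 3′ 30-mers 100%, 90.6% and 0% occurred in transcripts of another gene, which leaves the values of Rpl10 and Rps2 uncertain. Such copies were not found for Rpl21, and the cause of its low count was not tested. Of 15 listed ribosomal protein genes 3 fell (3 adjusted over the list alone, median -0.50, adjusted p = 0.00344, adjusted p = 0.502 with an estimated correlation).

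edgeR called 4210 of 11194 genes between PDGFB-WT and PDGFB-NLS in OPC-like cells, 2263 higher and 1947 lower in PDGFB-WT. Groups were apart, without overlap, at 3922 of called genes, and at 63.2% of tested genes. Chance gives 20%, or more if PDGFB-WT replicates 1 and 2, nearly alike, are not independent. A kit or run difference was not told apart from the group in any of these results. Signs of cell quality and depth moved with the groups. OPC-like cells had a median of 4.52%, 4.39% and 2.87% mitochondrial UMIs in PDGFB-WT against 2.92% and 2.50% in PDGFB-NLS, 1.07%, 0.916% and 1.69% of UMIs from Malat1 against 2.33% and 2.78%, and 2787, 2619.5 and 2503.5 UMIs against 4253 and 5817.5. OPC-like cells sat in different clusters by library. In PDGFB-WT replicates 1 and 2 they lay in clusters 0 (29.4% and 28.1%) and 4 (70.4% and 71.7%), while in PDGFB-WT replicate 3, PDGFB-NLS and Control nearly all lay in cluster 8. Without PDGFB-WT replicate 1, 2 or 3 the count was 1099, 1100 or 7665, and without PDGFB-NLS replicate 1 or 2 it was 37 or 26, with the lone PDGFB-NLS library assumed to vary like the other groups. Of 36 called genes named here 4 were still called without PDGFB-NLS replicate 1 and 3 without replicate 2. Without PDGFB-WT replicate 1 or 2, 22 or 23 of the 28 that were tested kept their call, and with DESeq2 35 did, Tmem125 losing it. With equal cells per library 6 of the 24 tested did, with 16 moved by over 1.5 times and Pdgfb and Tpx2 among those lost, and thinned to equal depth 18 of 26 did, with 15 moved by over 1.5 times.

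**Figure D2:**
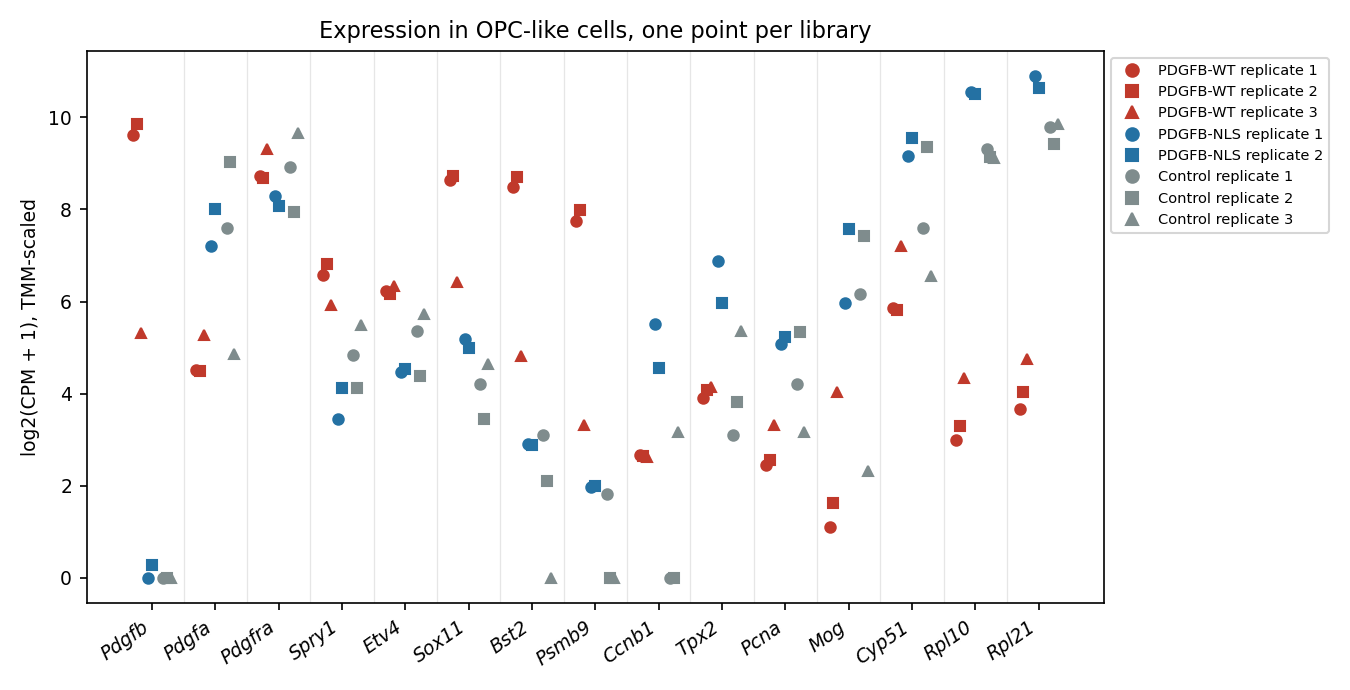
Each point is 1 library (PDGFB-WT, PDGFB-NLS or Control) and gives log2(CPM + 1), TMM-scaled, of a named gene in OPC-like cells, with genes on the horizontal axis. Pdgfb averages 582 CPM in PDGFB-WT and 0.106 CPM in PDGFB-NLS, while Tpx2 averages 15.6 and 89.5 CPM.

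PDGFB-WT was compared with Control in OPC-like cells. Pdgfb and egfp had 0 UMIs in Control, and their PDGFB-WT means were at least 170-fold and at least 731-fold higher. Replicate 3 lay far below both means, by the values above. Vim, an intermediate filament gene of immature glia, rose by 4.16 ± 0.41 (SE, adjusted p = 0.00162), from 19.4 ± 4.14 CPM in Control (SD, n = 3) to 341 ± 92.7 CPM (SD, n = 3). The neural progenitor genes Sox11 (303 ± 189 against 17.2 ± 7.13 CPM, adjusted p = 0.00622), Sox4 (log2 change 1.5 ± 0.24) and Dcx (2.09 ± 0.45) rose, as did the chromatin gene Hmga2 (at least 45.7-fold) and the muscarinic receptor gene Chrm3 (at least 50.9-fold). Dcx and Hmga2 lost their call at 5% mitochondrial UMIs, at 2000 UMIs and at Leiden resolution 2, and Hmga2 was the leading gene of cluster 0. Part of the target genes of p53 rose, among them the cell cycle inhibitor gene Cdkn1a (124 ± 71.9 against 8.21 ± 7.11 CPM, adjusted p = 0.011) and Zmat3 (49.7 ± 16.4 against 9.24 ± 5.86 CPM), while Eda2r was at 14.8 against 1.10 CPM (1 UMI). Pdgfra was 490 ± 125 against 513 ± 285 CPM (log2 change -0.07, adjusted p = 0.925). Pdgfa was 27.0 ± 9.05 against 248 ± 252 CPM (-3.28 ± 0.77, adjusted p = 0.0199), with overlapping groups and a sign that turned under other cell filters and a finer clustering (0.93 to 1.00).

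Of 10 neural progenitor genes 4 rose (4 adjusted over the list alone, median 2.46, or 1.78 with 4 members at their bound, adjusted p = 0.00474, adjusted p = 0.522 with an estimated correlation), and of 14 p53 targets 6 rose and 1 fell, the same numbers as adjusted over the list alone (median 1.18, adjusted p = 0.0295, adjusted p = 0.522 with an estimated correlation). Of 13 mesenchymal genes 8 rose (12 adjusted over the list alone, median 4.36, or 3.48 with 9 members at their bound, adjusted p = 1.46e-05, adjusted p = 0.522 with an estimated correlation), and Tnc was at 40.9 against 1.68 CPM (2 UMIs). Of 18 interferon genes 6 rose (17 adjusted over the list alone, median 8.44, or 3.48 with 12 members at their bound, adjusted p = 2.55e-05, adjusted p = 0.558 with an estimated correlation). Of 10 MHC class I genes 8 rose (10 adjusted over the list alone, median 4.85, or 4.15 with 5 members at their bound, adjusted p = 0.000112, adjusted p = 0.522 with an estimated correlation), and of 11 complement genes 8 rose (8 adjusted over the list alone, median 5.25, or 2.46 with 6 members at their bound, adjusted p = 1.46e-05, adjusted p = 0.522 with an estimated correlation). H2-K1, an MHC class I heavy chain gene, was at 1157 ± 960 against 29.7 ± 24.3 CPM, with overlapping groups, and Bst2 at 266 against 3.61 CPM. Tap1 was at least 17.9-fold higher, and Psmb8 was at 348 against 1.10 CPM (1 UMI). The free RNA ratios given above for interferon genes in PDGFB-WT apply here too. The signalling feedback genes Spred2 (2.19 ± 0.46) and Spry1 (1.64 ± 0.40) rose with 6 of 14 of their list (6 adjusted over the list alone, median 0.91, adjusted p = 0.00982, adjusted p = 0.522 with an estimated correlation).

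Part of the genes of respiration were higher in PDGFB-WT than in Control, with the ATP synthase gene Atp5b at 394 ± 6.72 against 148 ± 13.7 CPM (adjusted p = 0.00414). Of 14 oxidative phosphorylation genes 5 rose (8 rose and 1 fell adjusted over the list alone, median 0.71, adjusted p = 0.00485, adjusted p = 0.457 with an estimated correlation), and of 10 mitochondrial transcripts 9 rose (9 adjusted over the list alone, median 1.45, adjusted p = 1.35e-05, adjusted p = 0.522 with an estimated correlation). Cell quality also differed from the PDGFB-WT values above. OPC-like cells of Control had a median of 1.33%, 1.48% and 1.62% mitochondrial UMIs, and 7.68%, 6.50% and 6.76% of UMIs from the nuclear RNA Malat1. Of 14 myelin genes 4 were lower, among them Ugt8a at 144 ± 64.4 against 767 ± 616 CPM, the myelin regulator gene Myrf at 6.50 ± 4.43 against 57.8 ± 65.1 CPM with overlapping groups, and outside the list Elmod1 fell from 134 ± 124 to 3.73 ± 1.28 CPM. Adjusted over the list alone 4 fell as well (median -1.94, adjusted p = 0.0451, adjusted p = 0.752 with an estimated correlation). The cluster with Enpp6 and Gpr17 as leading genes given above may bear on these genes too. None of 20 G2/M genes passed the edgeR test, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 (median -0.69, or -0.72 with 4 members at their bound, adjusted p = 0.726, adjusted p = 0.921 with an estimated correlation). The median of these genes ranged from -1.42 to 1.17 when each library was left out. The ribosomal protein gene Rpl29, with 100% of its 3′ 30-mers in transcripts of another gene, was at 3.62 ± 1.37 against 187 ± 52.7 CPM.

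edgeR called 2644 of 11194 genes between PDGFB-WT and Control, 1390 higher and 1254 lower in PDGFB-WT. The groups did not overlap at 2386 of these and at 36.9% of tested genes, where chance gives 10%, or more as above. The effect of the technical difference given above stays open here too. The Control class held 44, 27 and 29 cells, with medians of 6643, 6623 and 7440 UMIs against 2503.5 to 2787 in PDGFB-WT. Without PDGFB-WT replicate 1, 2 or 3 the count was 842, 788 or 5191, without Control replicate 1 or 2 it was 644 or 1154, and without PDGFB-NLS replicate 1 or 2, which entered the shared model, 1625 or 1595. Of 24 called genes named here 9 stayed called without Control replicate 1, 14 without Control replicate 2 and 22 without Control replicate 3. Without PDGFB-WT replicate 1 or 2, 17 of the 21 tested did. At 5% mitochondrial UMIs 14 of 23 did, at 2000 UMIs 15 and at Leiden resolution 2 also 15, with Pdgfa, Dcx, Hmga2, Tap1, Elmod1, Spred2 and Spry1 lost under all 3. With equal cells per library 13 of 20 stayed called.

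PDGFB-NLS was compared with Control in OPC-like cells. The feature egfp had 0 UMIs in Control and was at least 3610-fold higher in PDGFB-NLS (12350 ± 9326 CPM, SD, n = 2). Pclaf, a gene of DNA replication, rose by 4.87 ± 0.66 (SE, adjusted p = 0.0409), from 6.82 ± 8.58 CPM in Control (SD, n = 3) to 189 ± 80.3 CPM. Vim rose by 4.01 ± 0.43 (adjusted p = 0.024), from 19.4 ± 4.14 to 308 ± 150 CPM. The ribosomal protein genes Rplp0 (2265 ± 443 against 428 ± 56.9 CPM), Rpsa (log2 change 2.17 ± 0.24), Rps4x (2.03 ± 0.24) and Rpl8 (1.82 ± 0.21) were higher, with 24.0%, 1.9%, 77.1% and 22.4% of their 3′ 30-mers in transcripts of another gene, and Angptl1 fell by 3.18 ± 0.43 (6.66 ± 1.10 against 61.2 ± 28.8 CPM). Pdgfa was 201 ± 77.4 against 248 ± 252 CPM (log2 change -0.31, adjusted p = 0.924) and Pdgfra 291 ± 29.4 against 513 ± 285 CPM (adjusted p = 0.511). The Pdgfa change lay between -0.84 and 0.82 when each library was left out.

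Lists of cell cycle genes were higher at the preset correlation, and none of the 3 kept its call with an estimated one. Over all genes none of 20 G2/M genes, 18 S phase genes or 17 spindle checkpoint and kinetochore genes passed in edgeR, where 11, 8 and 6 had an unadjusted p under 0.05 and DESeq2 called 1, 0 and 3. Adjusted over the list alone 6, 4 and 4 were higher. Their medians were 1.87, 1.35 (1.33 with 2 members at their bound) and 1.36, with adjusted p = 1.05e-12, 5.59e-09 and 5.1e-09, and adjusted p = 0.442, 0.22 and 0.442 with an estimated correlation. Spc24 was at 50.3 ± 18.8 against 3.78 ± 4.04 CPM (3 UMIs, adjusted p = 0.0698), Ccnb1 at 33.6 ± 15.7 against 2.68 ± 4.64 CPM (2 UMIs, adjusted p = 0.121) and Gins2 at 35.6 ± 15.5 against 2.68 ± 4.64 CPM (2 UMIs, adjusted p = 0.115). Of 15 ribosomal protein genes 2 rose (15 adjusted over the list alone, median 1.45, adjusted p = 0.103 with an estimated correlation). None of 14 dissociation stress genes passed over all genes in edgeR (8 at an unadjusted p under 0.05, 6 called by DESeq2), while 7 were lower and 1 higher adjusted over the list alone (median -0.88, or -1.07 with 1 member at its bound, adjusted p = 1.27e-05, adjusted p = 0.188 with an estimated correlation), and Jun was at 77.1 ± 2.60 against 361 ± 99.7 CPM (adjusted p = 0.0528).

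edgeR called 13 of 11194 genes between PDGFB-NLS and Control, 12 higher and 1 lower, with 1420 genes at an unadjusted p under 0.05 and 350 called by DESeq2 (250 higher, 100 lower). The groups did not overlap at any of the 13 and at 31.4% of all tested genes, where chance gives 20%. Cell quality and depth moved with these groups too. By the medians above, PDGFB-NLS had more mitochondrial UMIs, less Malat1 and fewer UMIs than every Control library. With equal cells per library 5 of the 8 called genes named here stayed called, and thinned to equal depth 7. The count was 0 without Control replicate 1 or 2, PDGFB-NLS replicate 1, or PDGFB-WT replicate 1 or 2, 1 without Control replicate 3 or PDGFB-NLS replicate 2, and 398 without PDGFB-WT replicate 3, where all 8 named genes stayed called.

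In astrocyte-like cells PDGFB-NLS was compared with Control, without telling changes of subtypes from changes within cells. Gfap, the astrocyte filament gene, was at 307 ± 132 (SD, n = 2) against 70.3 ± 40.9 CPM (SD, n = 3, edgeR adjusted p = 0.046), and Vim at 107 ± 44.5 against 33.0 ± 6.55 CPM. The matrix gene Tnc was at 52.3 ± 4.33 against 11 ± 2.69 CPM (adjusted p = 0.00299), and Thbs4, a synapse and matrix protein gene, at 39.7 ± 10.5 against 3.62 ± 3.61 CPM. Ppp1r1a rose by 2.73 ± 0.21 (SE, adjusted p = 0.0027), Fxyd6 by 2.92 ± 0.56 and the vessel growth factor gene Angpt1 by 2.19 ± 0.26. The MHC class I genes H2-D1 (1.29 ± 0.17) and H2-K1 (0.77 ± 0.13) and the interferon-induced chemokine gene Cxcl10 (2.42 ± 0.47) rose. Gfap and Cxcl10 lost their call with doublets kept, at Leiden resolution 2 and at 5% mitochondrial UMIs, and Fxyd6 with DESeq2, with doublets kept and at resolution 2. Rpe65 fell by 3.32 ± 0.39, the stress gene Nupr1 by 2.47 ± 0.37, Rcan2 by 2.13 ± 0.40, Cmss1 by 1.79 ± 0.14 and the sterol sensor gene Insig1 by 1.15 ± 0.20.

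Of 16 interferon genes in astrocyte-like cells 1 rose (6 adjusted over the list alone, median 1.65, adjusted p = 5.09e-07, adjusted p = 0.523 with an estimated correlation), of 8 MHC class I genes 2 rose (4 adjusted over the list alone, median 0.64, adjusted p = 0.000206, adjusted p = 0.523 with an estimated correlation) and of 11 mesenchymal genes 2 rose (7 rose and 1 fell adjusted over the list alone, median 1.65, adjusted p = 1.1e-05, adjusted p = 0.523 with an estimated correlation). None of 15 dissociation stress genes passed over all genes in edgeR (8 at an unadjusted p under 0.05, 1 called by DESeq2), with 4 higher adjusted over the list alone (median 0.80, adjusted p = 0.000133, adjusted p = 0.523 with an estimated correlation). Of 14 myelin genes 2 rose, among them Cldn11 (1.91 ± 0.34), with 12 adjusted over the list alone (median 1.52, adjusted p = 4.43e-10, adjusted p = 0.523 with an estimated correlation). The ratio of Cldn11 in astrocyte-like cells to barcodes with few UMIs was 0.0904 and 0.0965. Of 15 cholesterol synthesis genes 1 fell (3 adjusted over the list alone, median -0.27, adjusted p = 0.0029, adjusted p = 0.628 with an estimated correlation). edgeR called 198 of 12475 genes, 99 higher and 99 lower. The groups did not overlap at any of the 198 and at 38.2% of tested genes, where chance gives 20%. Without Control replicate 1, 2 or 3 the count was 36, 474 or 12, and without PDGFB-NLS replicate 1 it was 539. Of 16 named genes 8, 15 and 4 stayed called without Control replicates 1 to 3, and 15 and 10 without PDGFB-NLS replicates 1 and 2. At 5% mitochondrial UMIs 9 did and with equal cells per library 12. Cluster 14, with a median of 1299 UMIs and 0.229% Malat1, held 64.3% to 71.1% of the astrocyte-like cells of Control and 49.6% and 30.9% of those of PDGFB-NLS, and cluster 16, with 4005 UMIs and 5.92% Malat1, held the others.

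PDGFB-NLS was also compared with Control in microglia-like cells. Cd300lf, an immune receptor gene, was at 37.3 ± 4.84 in PDGFB-NLS (SD, n = 2) against 1.38 ± 1.30 CPM in Control (SD, n = 3, edgeR adjusted p = 0.0196). The cytokine gene Osm rose by 1.37 ± 0.18 (SE, adjusted p = 0.0459), Igfbp4 by 1.42 ± 0.20 and Rgs7bp by 1.5 ± 0.19. The fructose transporter gene Slc2a5 fell by 1.17 ± 0.15, Tmx4 by 1.74 ± 0.23 and Cmss1 by 1.39 ± 0.14, and Aqp12 had 0 UMIs in PDGFB-NLS and was at least 101-fold lower. Pdgfb was 44.6 ± 9.62 against 48.0 ± 8.11 CPM (log2 change -0.11, adjusted p = 0.834), and from -0.33 to 0.10 when each library was left out. No gene of 17 interferon, 14 disease-associated microglia and 6 MHC class II genes passed over all genes in edgeR, where 8, 5 and 3 had an unadjusted p under 0.05 and DESeq2 called 0, 2 and 1. Adjusted over the list alone 4 interferon genes were higher (median 0.90, adjusted p = 7.46e-06, adjusted p = 0.515 with an estimated correlation), 3 disease-associated microglia genes were higher (median 0.35, adjusted p = 0.00165, adjusted p = 0.515 with an estimated correlation) and 2 MHC class II genes were lower (median -0.75, adjusted p = 0.0165, adjusted p = 0.515 with an estimated correlation). The myelin gene Cnp rose by 1.40 ± 0.18 with a ratio to barcodes with few UMIs of 0.155 and 0.0914, and 9 of 14 myelin genes were higher adjusted over the list alone (1 over all genes, median 1.73, adjusted p = 3.68e-13, adjusted p = 0.515 with an estimated correlation). edgeR called 22 of 12010 genes, 8 higher and 14 lower, and DESeq2 163. Groups were apart at each of the 22 and at 33.2% of tested genes, where chance gives 20%. Without Control replicate 1, 2 or 3 the count was 9, 11 or 3, and without PDGFB-NLS replicate 1 or 2 it was 1 or 36. Of 9 called genes named here 1, 4 and 1 stayed called without Control replicates 1 to 3, 1 and 6 without PDGFB-NLS replicates 1 and 2, and 6 without PDGFB-WT replicate 3. Osm and Aqp12 lost their call with equal cells per library and when thinned to equal depth, and Osm, Igfbp4 and Tmx4 with only the 2 groups. Cluster 20 held 75% and 76.8% of microglia-like cells of PDGFB-NLS and 62.0%, 43.4% and 64.1% of those of Control, with most others in cluster 18.

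In endothelial-like cells, 4 of 13 angiogenesis genes were higher and 1 lower in PDGFB-NLS than in Control, and 5 of 8 collagen and matrix genes were higher, while neither list kept its call with an estimated correlation. Apln, a peptide gene of sprouting endothelium, was at 48.4 ± 1.31 (SD, n = 2) against 1.88 ± 0.981 CPM (SD, n = 3, edgeR adjusted p = 0.000132), its receptor gene Aplnr at 38.0 ± 2.53 against 4.85 ± 1.70 CPM, and Angpt2, a factor of vessel remodelling, at 25.9 ± 3.85 against 5.99 ± 2.33 CPM. The VEGF receptor gene Kdr rose by 0.54 ± 0.10 (SE, adjusted p = 0.00891). The basement membrane collagen genes Col4a1 (601 ± 26.1 against 222 ± 8.52 CPM, adjusted p = 0.000132) and Col4a2 (log2 change 1.35 ± 0.10) and the matrix protein gene Sparc (1.17 ± 0.09) rose, and the laminin gene Lamb1 was at 23.4 against 0.166 CPM (1 UMI). Fgfbp1 rose by 3.40 ± 0.28 and the integrin gene Itga4 by 2.69 ± 0.26. Among genes that were lower, Fmo2 fell by 4.04 ± 0.41, Xdh by 3.16 ± 0.24, the arterial gene Gkn3 by 2.99 ± 0.53, the clock output gene Dbp by 2.66 ± 0.32 (17.2 ± 2.70 against 109 ± 37.4 CPM), Zfp36 by 1.78 ± 0.20 and Egr1 by 1.39 ± 0.16. The antigen presentation genes Psmb8 (fell by 1.09 ± 0.14), H2-T23 (fell by 1.41 ± 0.20) and H2-K1 (fell by 0.69 ± 0.14) and the interferon gene Ifit3 (fell by 1.60 ± 0.29) were lower too, and Aqp12 had 0 UMIs and was at least 46.7-fold lower.

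The numbers given above for collagen and matrix genes (median 1.07, adjusted p = 4.83e-15, adjusted p = 0.315 with an estimated correlation) and angiogenesis genes (median 0.23, adjusted p = 3.95e-06, adjusted p = 0.404 with an estimated correlation) were the same adjusted over the list alone. Of 10 MHC class I genes 6 fell (7 adjusted over the list alone, median -0.89, adjusted p = 1.22e-07, adjusted p = 0.404 with an estimated correlation) and of 17 interferon genes 4 fell (7 adjusted over the list alone, median -0.43, adjusted p = 9.62e-05, adjusted p = 0.537 with an estimated correlation). Of 15 dissociation stress genes 11 fell and 1 rose, the same numbers as adjusted over the list alone (median -0.87, adjusted p = 5.19e-12, adjusted p = 0.53 with an estimated correlation). Of 13 myelin genes 5 rose (6 adjusted over the list alone, median 1.41, adjusted p = 4.93e-06, adjusted p = 0.537 with an estimated correlation). The median ratio of 17 myelin and OPC genes in endothelial-like cells to barcodes with few UMIs was 0.082 and 0.088 in PDGFB-NLS. edgeR called 936 of 10764 genes in endothelial-like cells, 442 higher and 494 lower, and DESeq2 called 493. The groups did not overlap at 934 of these and at 41.0% of tested genes, where chance gives 20%. Depth and cell quality moved with the groups, with medians of 2583 and 2951 UMIs in PDGFB-NLS against 4167.5, 3975 and 4957 in Control, 2.15% and 2.21% of UMIs from Malat1 against 3.04%, 2.78% and 3.05%, and 3.39% and 2.8% mitochondrial UMIs against 2.65% to 2.66%. With equal cells per library and when thinned to equal depth all 21 named genes stayed called. Without Control replicate 3 the count was 395, and without PDGFB-NLS replicate 1 or 2 it was 341 or 501. Kdr, Gkn3, H2-K1 and Ifit3 lost their call without PDGFB-NLS replicate 1, and H2-K1 without Control replicate 3. Under 2 other cell filters and a finer clustering, 24 to 88 endothelial-like cells of PDGFB-WT replicates 1 and 2 entered the shared model and 2 to 18 genes were called, while models of only the 2 groups on the same cells called 921 to 1002. Of the 21 named genes 1, 4 and 3 stayed called at 5% mitochondrial UMIs, at 2000 UMIs and at Leiden resolution 2 in the shared model, and all 21 in each model of only the 2 groups.

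**Figure D3:**
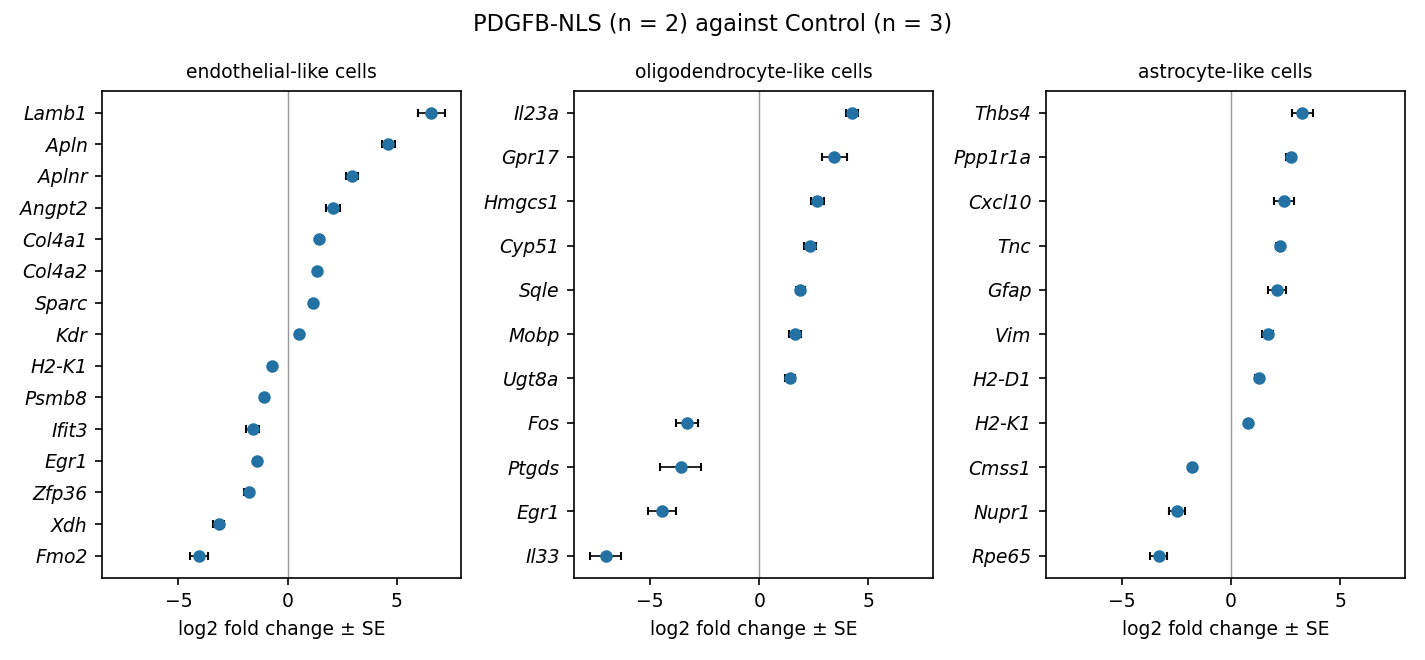
Points give the log2 fold change of PDGFB-NLS against Control on the horizontal axis, with bars for the SE, for named genes of endothelial-like, oligodendrocyte-like and astrocyte-like cells. Apln and Col4a1 are at 4.62 and 1.44 in endothelial-like cells, Il33 is at -7.04 in oligodendrocyte-like cells, and the value of Lamb1 is a fitted one against 1 UMI in Control.

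In oligodendrocyte-like cells, PDGFB-NLS was compared with Control for the myelinating lineage. Of 15 cholesterol synthesis genes 11 rose in PDGFB-NLS, but the list lost its call with an estimated correlation (adjusted p = 0.613). Hmgcs1 was at 1325 ± 394 (SD, n = 2) against 211 ± 9.41 CPM (SD, n = 3, edgeR adjusted p = 0.00099), Cyp51 at 1092 ± 214 against 219 ± 32.4 CPM and Sqle at 131 ± 36.8 against 35.6 ± 4.43 CPM. Gpr17, a receptor gene of newly forming oligodendrocytes, rose by 3.44 ± 0.56 (SE, adjusted p = 0.00576), Il23a by 4.24 ± 0.28, the myelin gene Mobp by 1.64 ± 0.25 and Ugt8a by 1.41 ± 0.24. Il33, an alarmin gene of mature oligodendrocytes, was at 4.14 ± 0.331 against 566 ± 129 CPM (fell by 7.04 ± 0.70, adjusted p = 0.000645), and Ptgds, a prostaglandin synthase gene, fell by 3.61 ± 0.95. The immediate early genes Egr1 and Fos fell by 4.48 ± 0.64 and 3.32 ± 0.50, and Aqp12 had 0 UMIs and was at least 243-fold lower. Adjusted over the list alone 14 cholesterol genes rose (median 1.75, adjusted p = 2.65e-19), and 6 of 15 myelin genes did, as over all genes (median 1.01, adjusted p = 0.0026, adjusted p = 0.78 with an estimated correlation). Of 14 OPC genes 3 rose (7 rose and 1 fell adjusted over the list alone, median 1.98, or 1.97 with 4 members at their bound, adjusted p = 0.000445), and of 15 dissociation stress genes 7 fell (7 adjusted over the list alone, median -1.42, adjusted p = 0.000162), both with adjusted p = 0.773 with an estimated correlation. edgeR called 890 of 10371 genes, 459 higher and 431 lower. Groups were apart at each of the 890 and at 55.3% of tested genes, where chance gives 20%. Without Control replicate 1, 2 or 3 the count was 277, 357 or 243, without PDGFB-NLS replicate 1 or 2 it was 201 or 286, and without PDGFB-WT replicate 3 it was 2739. Of 12 named genes 10 stayed called without PDGFB-NLS replicate 1 (Gpr17 and Ptgds lost), 8 without replicate 2 (Ugt8a, Ptgds, Egr1 and Aqp12 lost), 11 without Control replicate 1 or 2 and 10 without Control replicate 3. The class sat in cluster 12 for 77.3% to 79.3% of its Control cells and for 41.3% and 65.4% of its PDGFB-NLS cells, of which 55.1% and 28.4% lay in cluster 19, with a median of 1422 UMIs.

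The other comparisons gave these counts with edgeR. In oligodendrocyte-like cells, 2660 genes were called between PDGFB-WT and PDGFB-NLS (1253 higher, 1407 lower), and the count was 846 or 618 without PDGFB-NLS replicate 1 or 2 and 4196 without PDGFB-WT replicate 3. Between PDGFB-WT and Control 2040 were called (983 higher, 1057 lower), with 579, 665 or 496 without Control replicate 1, 2 or 3 and 1198, 1179 or 3744 without PDGFB-WT replicate 1, 2 or 3. These cells lay in cluster 9 in PDGFB-WT replicates 1 and 2 and in cluster 12 for 94.2% in replicate 3. In fibroblast-like cells 27 genes were called between PDGFB-WT and PDGFB-NLS (3 higher, 24 lower) and 44 between PDGFB-WT and Control (12 higher, 32 lower). DESeq2 turned this balance, with 96 higher and 42 lower, and 113 higher and 67 lower. Without Control replicate 2 or 3 these counts were 6 and 9, or 12 and 5, without PDGFB-NLS replicate 1 or 2 they were 1 and 9, or 7 and 9, and without PDGFB-WT replicate 1, 2 or 3 they were 7 and 11, 7 and 10, or 2134 and 2069. No fibroblast-like gene was called by edgeR or DESeq2 between PDGFB-NLS and Control, where 234 of 5308 had an unadjusted p under 0.05 in edgeR. Fibroblast-like cells lay in cluster 3 in PDGFB-WT replicates 1 and 2 and in cluster 23 in the others.

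Over the sum of all cells, which mixes composition with expression, edgeR called 1719 genes between PDGFB-WT and PDGFB-NLS (839 higher, 880 lower) and 4536 between PDGFB-WT and Control (2905 higher, 1631 lower). It called none of 17049 between PDGFB-NLS and Control, where 1533 had an unadjusted p under 0.05 and DESeq2 called 346. These counts turned on single libraries. Without PDGFB-WT replicate 1, 2 or 3 they were 11, 24 or 9719 for PDGFB-WT with PDGFB-NLS, 329, 253 or 11041 for PDGFB-WT with Control, and 0, 0 or 898 for PDGFB-NLS with Control. Without PDGFB-NLS replicate 1 or 2 they were 98 or 8 for PDGFB-WT with PDGFB-NLS and 3011 or 3113 for PDGFB-WT with Control. Without Control replicate 1, 2 or 3 they were 215, 260 or 53 for PDGFB-WT with PDGFB-NLS and 396, 581 or 60 for PDGFB-WT with Control.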

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

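The tests of a kit or run difference, of a change confined to OPC-like cells, of the 2 groups alone at Leiden resolution 2, and of other splits for OPC-like cells and for all cells were chosen after the results had been seen. Other tests of causes were written before.

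The interaction of class and group compared effects of PDGFB-NLS against Control between classes. For 18 interferon genes the median log2 difference, astrocyte-like minus endothelial-like, was 2.157, with 8 genes called (adjusted p = 5.82e-08). For 10 MHC class I genes it was 1.597, with 6 called (adjusted p = 6.26e-08), and for 15 dissociation stress genes 1.872, with 10 called (adjusted p = 1.3e-07). For these lists, microglia-like minus endothelial-like gave 1.476, 0.871 and 0.575 (adjusted p at most 1.38e-06). Astrocyte-like minus oligodendrocyte-like gave 0.334, 1.019 and 1.986 (adjusted p = 0.169, 0.0789 and 1.51e-05). With an estimated correlation none passed (adjusted p = 0.387, 0.367 and 0.367 for the first pair). Barcodes with few UMIs, used in no comparison of genes and only 1 alternative for shares, held egfp at 1304.7, 1308.8 and 7.1 CPM in PDGFB-WT replicates 1 to 3 and at 896.9 and 278.6 CPM in PDGFB-NLS, with 0 in Control.

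Interferon and MHC class I genes were higher in OPC-like cells of PDGFB-WT than of PDGFB-NLS. The median ratio of the 28 called genes to barcodes with few UMIs was 1.03 and 1.00 in PDGFB-WT replicates 1 and 2, above the upper quartile of T/NK and macrophage markers there (0.336 and 0.38). In replicate 3 it was 0.212, next to 0.165 for those markers, so free RNA from immune cells may account for part of the counts and stays open. A kit or run difference cannot be told apart from the group, since PDGFB-WT libraries shared at most 2 barcodes with any other library. An effect of the construct also stays open, as no test here separates it from these.

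Of 80 ribosomal protein genes tested in OPC-like cells, 23 were called lower and 8 higher in PDGFB-WT than in PDGFB-NLS. Reads shared with copies may contribute, since a median of 74.9% of the 3′ 30-mers of the 23 genes occurred in transcripts of another gene against 39.3% of the 57 others, but this difference of 35.6 points had a permutation p of 0.163 and stays open. Of the 23 genes 10 were also called lower in both oligodendrocyte-like and fibroblast-like cells, and 2 more in oligodendrocyte-like cells, which leaves open whether the other 11 changed in OPC-like cells alone. A biological difference between the groups was not separated from these.

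Between PDGFB-NLS and Control, 5 of 13 myelin, 3 of 5 OPC and 5 of 8 collagen and matrix genes were called higher in endothelial-like cells. In microglia-like cells edgeR called 1 of 14 myelin genes and none of 7 OPC genes, of which 4 had an unadjusted p under 0.05, 0 were called by DESeq2 and 3 were higher adjusted over the list alone. With an estimated correlation the myelin and OPC lists had adjusted p = 0.537 and 0.315, or 0.515 and 0.515 in microglia-like cells. For the myelin and OPC genes with a rise the highest median ratio to barcodes with few UMIs was 0.134, and in those barcodes PDGFB-NLS was above Control by a median of 2.06 on the log2 scale, which is consistent with free RNA. For the 5 collagen genes the lowest median ratio was 22.7, which argues against free RNA as their source as far as barcodes with few UMIs measure it. That endothelial cells expressed more collagen in PDGFB-NLS is a hypothesis, since animal and handling differences were not tested. At Leiden resolution 2 Col4a1 and Col4a2 lost their call in the model of all groups and were called in a model of the 2 groups on the same cells (log2 change 1.45 and 1.36).

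For PDGFB-WT against Control, the 10 splits of the 6 libraries are too few for a share under 0.05. In models of the 2 groups, the real split gave 1683, 1412 and 3307 genes in OPC-like cells, oligodendrocyte-like cells and the sum of all cells. The highest other split gave 1, 0 and 11, and 1 of the 10 splits reached the real count in each.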

How the results depend on the processing

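The alternatives chosen after the data had been seen are named above. Of 148 named gene results under all alternatives, 2241 values kept direction and side of the threshold, 474 lost their call, 17 gained one and 17 changed sign. Of 56 list results, 55 lost their call with an estimated correlation. Leaving out 1 library, 17 of 406 list values lost it, 387 kept direction and side of the threshold, 1 gained a call and 1 changed sign. Of the 17 gene counts, 135 values stayed within 1.5 times of the reported count and 167 did not. RLE scaling moved 1 count. Except where an alternative itself removes cells, genes, counts or libraries, the cause of a change was not tested.

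In OPC-like cells the PDGFB-WT against PDGFB-NLS count (4210) was 1148 with PDGFB-WT replicates 1 and 2 as 1 sample, 97 with equal cells per library and 700 when thinned to equal depth. The PDGFB-WT against Control count (2644) was 1683 with only the 2 groups, 814 with replicates 1 and 2 as 1 sample, 505 with equal cells, 1025 thinned, 1425 at 5% mitochondrial UMIs, 1423 at 2000 UMIs and 1000 genes and 1534 at Leiden resolution 2. The PDGFB-NLS against Control count (13) was 7 with RLE, 416 without the expression filter, 350 with DESeq2, 83 with only the 2 groups, 0 with replicates 1 and 2 as 1 sample, 7 with equal cells, 177 at 5% mitochondrial UMIs, 153 at 2000 UMIs, 24 with doublets kept and 166 at resolution 2. Leaving out each library gave 26 to 7665, 644 to 5191 and 0 to 398 for these 3 counts.

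In the sum of all cells the PDGFB-WT against PDGFB-NLS count (1719) was 1051 without the filter, 5012 with DESeq2, 4 with only the 2 groups and 17 with replicates 1 and 2 as 1 sample, the PDGFB-WT against Control count (4536) was 315 with replicates 1 and 2 as 1 sample, and the PDGFB-NLS against Control count (0) was 346 with DESeq2 and 75 with only the 2 groups. Leaving out each library gave 8 to 9719, 60 to 11041 and 0 to 898. In oligodendrocyte-like cells PDGFB-WT against PDGFB-NLS (2660) gave 432 with only the 2 groups and 1160 thinned, PDGFB-WT against Control (2040) gave 903 thinned, and PDGFB-NLS against Control (890) gave 1434 without the filter, 2870 with only the 2 groups, 458 with equal cells and 214 thinned. Leaving out each library gave 618 to 4196, 496 to 3744 and 201 to 2739. In fibroblast-like cells PDGFB-WT against PDGFB-NLS (27) gave 1011 without the filter, 138 with DESeq2, 12 with only the 2 groups, 7 with replicates 1 and 2 as 1 sample, 9 with equal cells, 17 thinned and 15 at 5% mitochondrial UMIs. PDGFB-WT against Control (44) gave 1154 without the filter, 180 with DESeq2, 10 with only the 2 groups, 11 with replicates 1 and 2 as 1 sample, 26 with equal cells and 26 thinned, and PDGFB-NLS against Control (0) gave 19 without the filter. Leaving out each library gave 1 to 2134, 5 to 2069 and 0 to 0.

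Between PDGFB-NLS and Control, astrocyte-like cells (198) gave 359 genes with DESeq2, 94 at 5% mitochondrial UMIs and 1036 at 2000 UMIs (12 to 539 leaving out each library). Endothelial-like cells (936) gave 493 with DESeq2, 2 at 5% mitochondrial UMIs, 18 at 2000 UMIs and 10 at resolution 2 (341 to 994). On the same cells, models of only the 2 groups gave 921, 936 and 1002, so the drop came with the PDGFB-WT cells that entered the shared model. Microglia-like cells (22) gave 1034 without the filter, 163 with DESeq2, 12 thinned, 149 at 5% mitochondrial UMIs, 198 at 2000 UMIs and 87 at resolution 2 (1 to 36). Mural-like cells (67) gave 152 without the filter, 17 with DESeq2, 36 with only the 2 groups, 18 with equal cells, 28 at 5% mitochondrial UMIs, 22 at 2000 UMIs and 112 with doublets kept (16 to 168). Neuroblast-like cells (8) gave 353 without the filter, 62 with DESeq2, 5 with equal cells, 14 thinned, 0 at 5% mitochondrial UMIs and 0 at resolution 2 (0 to 18). DESeq2 changed the balance of directions in OPC-like cells for PDGFB-NLS against Control and in fibroblast-like cells for both PDGFB-WT comparisons.

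A replicate block, which pairs libraries by their number, gave 6 genes in OPC-like cells between PDGFB-NLS and Control, 17 and 2967 in the sum of all cells for PDGFB-WT against PDGFB-NLS and against Control, 326 in fibroblast-like cells for PDGFB-WT against PDGFB-NLS, and 217, 0, 105 and 1 in endothelial-like, microglia-like, mural-like and neuroblast-like cells between PDGFB-NLS and Control. With the block the log2 change of Pdgfb in microglia-like cells was 0.03 and that of Pdgfra in OPC-like cells between PDGFB-WT and Control 0.05. Whether the numbers pair libraries stays open. Correlations of libraries with the same number had mixed signs, such as 0.087 and -0.096 between PDGFB-WT and PDGFB-NLS in OPC-like cells. These signs cannot decide it, since the deviations of the PDGFB-NLS libraries from their group mean mirror each other and PDGFB-WT replicates 1 and 2 were nearly alike.

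Some signs changed. The change of Pdgfa between PDGFB-WT and Control (-3.28) was 1.00 at 5% mitochondrial UMIs, 0.93 at 2000 UMIs and 1.00 at resolution 2, and between PDGFB-NLS and Control (-0.31) it was 1.16, 1.23 and 1.21 (-0.84 to 0.82 leaving out each library). Pdgfra between PDGFB-WT and Control (-0.07) was 0.06 without the filter and 0.05 with replicates 1 and 2 as 1 sample (-0.40 to 0.40), Pdgfb in microglia-like cells was -0.33 to 0.10, and the G2/M list in OPC-like cells between PDGFB-WT and Control -1.42 to 1.17. In percentage points, the astrocyte-like share of PDGFB-NLS minus Control (-2.95) was 0.31 at resolution 2 and 1.90 at 2000 UMIs (-7.70 to 1.80), the oligodendrocyte-like share (-0.33) 0.12 at resolution 2 and 3.22 at 500 UMIs (-5.67 to 5.02), the microglia-like share (4.45) -3.06 to 11.96 and the macrophage-like share -0.08 at 5% mitochondrial UMIs. At 500 UMIs the macrophage-like share was -0.32, -0.24 and -0.11 for PDGFB-WT against PDGFB-NLS, PDGFB-WT against Control and all PDGFB libraries against Control, and this filter gave no value for 4 of the 28 share results. The neuroblast-like share of PDGFB-WT minus Control (-0.52) was 0.93 at resolution 2. The cycling share of PDGFB-WT minus Control (0.69) was -0.50 to 1.35, and that of all PDGFB libraries minus Control (2.39) was 5.53 when thinned to 2000 UMIs (exact permutation p = 0.0357). OPC-like shares of all kept cells are given above. Small changes could be missed, as the simulated 2-fold changes show, and whether depth, cell number or spread set this was not tested.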

Other observations

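All tests in this part were planned, while the genes described in words were picked from those the naming rule selected. In mural-like cells, the pericytes and smooth muscle cells of vessels, 6 of 9 collagen and matrix genes were higher in PDGFB-NLS than in Control. Their list lost its call with an estimated correlation (adjusted p = 0.112). PDGFB-NLS had fewer UMIs (medians of 1506 and 1852 against 2668, 2352.5 and 2837), less Malat1 and more mitochondrial UMIs than every Control library. Col4a1 was at 1158 ± 195 (SD, n = 2) against 305 ± 56.7 CPM (SD, n = 3, edgeR adjusted p = 1.18e-05), Col4a2 rose by 1.86 ± 0.26 (SE), the fibrillar collagen gene Col3a1 by 2.12 ± 0.36, the elastin gene Eln by 3.20 ± 0.71 and Ppic by 2.98 ± 0.38. Adjusted over the list alone 8 matrix genes rose (median 1.86, adjusted p = 1.01e-20). The clock output gene Dbp fell by 2.28 ± 0.30 (69.0 ± 4.79 against 340 ± 33.1 CPM), and the clock gene Per3 was at 7.29 CPM (2 UMIs) against 96.3 CPM. Aqp12 had 0 UMIs in PDGFB-NLS and was at least 10.2-fold lower. edgeR called 67 of 4635 genes, 41 higher and 26 lower. Without Control replicate 2 or 3 the count was 168 or 37, without PDGFB-NLS replicate 1 it was 16 and without PDGFB-WT replicate 3 it was 36. Col3a1, Eln, Per3 and Aqp12 lost their call without PDGFB-NLS replicate 1, Eln without PDGFB-NLS replicate 2, and Per3 without Control replicate 3 or PDGFB-WT replicate 3. Eln and Per3 lost it with DESeq2, Col3a1, Per3 and Aqp12 with equal cells per library, Per3 with only the 2 groups and at 5% mitochondrial UMIs, and Aqp12 at 2000 UMIs.

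In neuroblast-like cells, egfp had 0 UMIs in Control and was at least 1676-fold higher in PDGFB-NLS. This bound used the mean of replicates 1 and 2, at 20640 and 3360 CPM, so replicate 2 alone gives one over 3 times lower. Fabp7, a lipid-binding protein gene of neural progenitors, rose by 3.24 ± 0.30 (SE, edgeR adjusted p = 0.00454), from 238 ± 13.4 (SD, n = 3) to 2245 ± 944 CPM (SD, n = 2), and the mitotic gene Ube2c was at 566 ± 32.2 against 69.8 ± 38.6 CPM. The long noncoding RNA genes Meg3 and Malat1 fell by 2.14 ± 0.29 and 1.35 ± 0.19. Of 13 G2/M genes 1 rose (10 adjusted over the list alone, median 1.79, adjusted p = 4.48e-17, adjusted p = 0.277 with an estimated correlation), and none of 9 spindle checkpoint and kinetochore genes passed over all genes in edgeR (7 at an unadjusted p under 0.05, 0 called by DESeq2), with 6 higher adjusted over the list alone (median 1.39, adjusted p = 1.83e-08, adjusted p = 0.447 with an estimated correlation). A UMI of Mki67 or Top2a after thinning to 1000 UMIs was seen in 17.8% and 18.8% of these cells in PDGFB-NLS (0.462% and 1.00% of microglia-like cells), and in 15.4%, 5.71% and 4.35% in Control, which held 26, 35 and 23 such cells. edgeR called 8 of 4665 genes, 5 higher and 3 lower, and DESeq2 62. Without Control replicate 1, 2 or 3 the count was 1, 4 or 0, and without PDGFB-NLS replicate 2 it was 18. Of the 5 named genes 1, 3 and 0 stayed called without Control replicates 1 to 3, and 4 without PDGFB-NLS replicate 2. All 5 lost their call at 5% mitochondrial UMIs and at Leiden resolution 2. At resolution 2 the cells of both groups lay in a cluster led by Ube2c and egfp with a median Malat1 share of 0 (369 and 163 cells of PDGFB-NLS against 14, 15 and 13 of Control) and in another with 2.73% Malat1 (64 and 148 against 13, 20 and 10). Within these clusters the changes of Ube2c, Meg3 and Malat1 were not tested.

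Within the OPC-like cells of PDGFB-WT replicates 1 and 2, pdgfb_nls and Pdgfb lay in cluster 4, as egfp did. There pdgfb_nls was at 7104 and 8513 CPM and Pdgfb at 957 and 1108 CPM. In cluster 0 pdgfb_nls was at 364 and 509 CPM and Pdgfb at 49.8 and 80.7 CPM. These values were near those of T/NK-like cells in the same libraries, with pdgfb_nls at 484 and 533 CPM and Pdgfb at 62.2 and 78.2 CPM. In endothelial-like cells Pdgfb was at 103 and 98.1 CPM in PDGFB-NLS and at 131, 124 and 105 CPM in Control.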
